A study of Schizosaccharomyces pombe with 8 samples.

How the data were processed

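RNA sequencing counts were analysed from 8 libraries of Schizosaccharomyces pombe in 4 groups of 2: wild type and strains labelled as lacking nht1, iec1 or iec5. Per the labels' protocols, cells grew to mid-log phase in rich YEA medium, total RNA was isolated with a MasterPure kit and depleted of ribosomal RNA with RiboMinus, and strand-specific libraries were made with an NEBNext Ultra II Directional kit. The counts of both deposited tables, 1 of coding and 1 of noncoding features, were made by the authors. Per the submitters' processing notes, reads were aligned with HISAT2 2.1.0 to build ASM294v2 and counted with featureCounts 1.6.1, and the authors tested differences with DESeq2 1.28.0. The strand setting of the counting step, the handling of reads that map to several places and any read filtering are not given in the sources used here. The authors' own test results were not used here.

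The coding table holds 5137 features, of which 5115 matched the RefSeq annotation of build ASM294v3 and 4261 carry a symbol there. The noncoding table holds 1528 features, of which 1428 matched. Of matched chromosomal features, 99.8% (coding) and 99.6% (noncoding) share a start or an end with the newer build. That annotation was used only for symbols, products, gene order and lengths, and the coordinates given are those of the files, on ASM294v2. Noncoding features were sorted into those overlapping no coding gene (426), those overlapping one on the opposite strand alone (812) and those overlapping one on their own strand (290).

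Coding totals per library were 3273405 and 3264745 (wild type), 3235768 and 2762696 (nht1), 2208165 and 3403361 (iec1) and 2977782 and 3426063 (iec5). The 10 most counted coding genes took 8.54% to 10.5% of coding counts, and mitochondrial genes 2.03% to 2.42%. Counts scaled by library size are given as CPM, and a count of 3 equals 0.876 to 1.36 CPM. Between replicates, the chi-square per degree of freedom was 7.07 to 9.56, so scatter was well above counting error, and the correlation of log2 CPM across genes was 0.981 to 0.986.

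Coding genes were tested with the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3, after TMM normalization and the default low-count filter of edgeR, in 1 fit of all 8 libraries. This left 4652 coding genes with a biological coefficient of variation of 11.9%. Noncoding features, of which 1096 were tested, took the library sizes and TMM factors of the coding table, and had a coefficient of 13.1%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold change. Each deletion was compared with wild type and with each other deletion. Fold changes are log2, and their standard errors are approximate, as the absolute log2 fold change over the square root of F. Gene lists (25, with 827 symbols matched and 47 not) were tested with camera of limma 3.58.1 with a preset correlation of 0.01, for lists with at least 5 tested genes, on log2 CPM with a prior count of 2. The subtelomeric list took genes within 100 kb of the ends of chromosomes I and II. Adjusted p-values throughout are from edgeR, or from camera in limma for lists, with Benjamini-Hochberg adjustment.

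Grouping, tests, thresholds, lists, alternatives and the rule for naming genes were set before the data were examined. The rule named, for each deletion against wild type, the deleted gene and the 10 largest rises and 10 largest falls with adjusted p under 0.05, a mean log2 CPM above 2 and both deletion libraries on the same side of both wild-type libraries. Between deletions and among noncoding features it named 5 each way. From each list it named up to 4 passing members with the largest change, or up to 2 with the smallest p where none passed, and among genes changed in all 3 deletions the 5 largest each way. Genes with counts of 0 in a group are given as a fold of at least the ratio to a floor of 3 counts per library, or as a ratio of pooled counts with an exact conditional 95% interval.

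The alternatives were DESeq2 1.42.0, RLE normalization (for noncoding features their own normalization), no low-count filter, a replicate block, fits of 2 groups only, an absolute log2 fold change of at least 1, and 8 fits that each left out 1 library. For lists they were an estimated correlation, fry, the block and RLE. Noncoding features that overlap no coding gene were also tested alone, a choice made after the data were seen. The tests were checked on simulated data: of coding genes changed 1.5-fold, 41.8%, 32.8% and 43.3% were recovered for nht1, iec1 and iec5, of those changed 2-fold 83.6%, 83.6% and 95.5%, and of those changed 4-fold 95.5%, 95.5% and 97.0%. Of 4452 unchanged genes 8, 5 and 5 were called. Shared calls were compared with 100 simulated draws of unchanged groups. Each draw made all libraries anew around the wild-type means, with 1 simulated wild-type group common to the 3 comparisons. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Nothing in the sources used here says that the 2 libraries of a group come from separate cultures, so the p-values measure only the spread between these samples. Some of the genes that the naming rule picked are not reported here. No sample or column was left out, and sequence reads were not analysed here.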

Results

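RNA was sequenced in 8 libraries of the fission yeast Schizosaccharomyces pombe, with 2 libraries from each of 4 groups: a wild-type strain and 3 strains labelled as lacking a subunit of INO80, a complex that moves and remodels nucleosomes. The genes named by the labels are nht1, which encodes an HMG-box protein, and iec1 and iec5. The series title places the work in the study of how heterochromatin is inherited. Cells grew to mid-log phase in YEA, a rich yeast extract medium, and the total RNA was depleted of ribosomal RNA before strand-specific libraries were made. Total counts over 5137 coding features ran from 2208165 (iec1 replicate 1) to 3426063 (iec5 replicate 2). Over 1528 noncoding features they ran from 374760 to 540394, of which 21.2% to 29.3% fell in the single feature SPNCRNA.98. Both libraries of a group lay on the same side of 0 on the first principal component, which held 42.4% of the variance. Wild type and iec5 lay on the negative side, and nht1 and iec1 on the positive side.

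The reads of each deleted gene were examined in every group as a check of the labels. The iec5 gene (SPAPB1E7.14, chromosome I, 3321855 to 3323689 on build ASM294v2) had 2.38 ± 1.30 CPM (counts scaled by library size) in the iec5 libraries and 12.6 ± 0.325 in wild type (SD, n = 2 each), or 18.8% of the wild-type level. The nht1 gene (SPAC10F6.08c, chromosome I, 1219667 to 1220847) had 29.9 ± 7.12 in the nht1 libraries and 45.1 ± 4.98 in wild type (SD, n = 2 each), or 66.3%. That difference did not pass the edgeR quasi-likelihood test (log2 fold change -0.60, SE 0.24, Benjamini-Hochberg adjusted p = 0.212). The iec1 gene (SPAC144.02, chromosome I, 4652937 to 4654387) was higher in the libraries labelled iec1 than in wild type, at 91.9 ± 4.93 against 38.4 ± 2.89 CPM (SD, n = 2 each; log2 fold change 1.25, SE 0.21, edgeR adjusted p = 0.000741). Reads of iec1 therefore go against the label of those libraries, and every direction given for them is that of the libraries labelled iec1. The loss of nht1 was not seen in its reads either, so nht1 is likewise used as the label of those libraries. Of the counted length of these features, 13.1% (nht1), 48.3% (iec1) and 76.3% (iec5) lies outside the annotated coding sequence, and the part removed in each strain is not given in the sources used here. The iec5 feature also overlaps mns1. Its call (log2 fold change -2.41, edgeR adjusted p = 0.0278) ended without either library of wild type, nht1 or iec5 in turn (adjusted p = 0.0527 to 0.417).

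**Figure D1:**
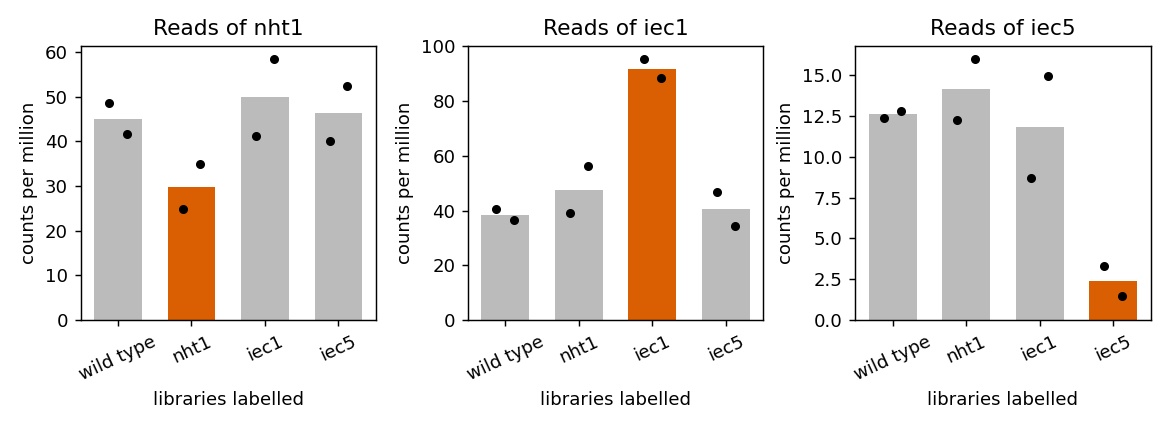
CPM (vertical axis) of nht1, iec1 and iec5 in the libraries of each label (horizontal axis); each point is 1 library, each bar the mean of 2, and the orange bar marks the strain labelled as lacking that gene. The orange bar stands at 66.3% of wild type for nht1, 239% for iec1 and 18.8% for iec5.

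The libraries labelled nht1 were compared with wild type. Of 4652 coding genes tested, 146 rose and 46 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). A block on the replicate number gave 263 and 93. The gene osr1 (SPCC663.06c, annotated as a dehydrogenase; chromosome III, 1644754 to 1645876) rose from 39.4 ± 8.29 to 289 ± 70.4 CPM (SD, n = 2 each; log2 fold change 2.87, SE 0.23, adjusted p = 1.3e-06). The nearby short chain dehydrogenase gene SPCC663.08c rose by 2.34 (SE 0.19), the Dis3-like exonuclease gene SPBC609.01 by 2.21 (SE 0.18), and the methyltransferase gene SPCC70.08c 4.28-fold. The gene caf5, for a plasma membrane spermine transporter, rose by 2.14 (SE 0.22), and nur1, whose product partners the inner nuclear membrane protein Lem2, by 1.87 (SE 0.32). Among genes that fell, dus2, for a tRNA dihydrouridine synthase, dropped from 146 ± 15.9 to 34.7 ± 0.736 CPM (SD, n = 2 each; log2 fold change -2.07, SE 0.18, edgeR adjusted p = 1.8e-06). The cytochrome oxidase assembly gene cox20 stood at -1.25 (SE 0.18), the aldo/keto reductase gene SPBC215.11c at -1.20 (SE 0.14) and cnp3, which encodes the fission yeast CENP-C, at -1.05 (SE 0.17). The rises of rec10 (1.89, SE 0.23), atg1801 (1.85, SE 0.25) and SPCC777.03c (1.77, SE 0.25), and the falls of his6 (-1.77, SE 0.24), SPBC887.17 (-1.48, SE 0.15) and tyr1 (-1.11, SE 0.17), are uncertain as to gene, because each overlaps another annotated gene. The fall of hpz2 (-2.64, SE 0.58) and that of SPBC530.07c (-1.57, SE 0.32) lost their calls without wild-type replicate 1 or either nht1 library (adjusted p = 0.0849 to 0.162 and 0.0673 to 0.107). The rise of uro1, for uricase (1.71, SE 0.34), lost its call without wild-type replicate 1 or nht1 replicate 2 (adjusted p = 0.114 to 0.158), and that of nur1 without wild-type replicate 2 (0.0614). The count of 192 was 90 without wild-type replicate 1, 70 without wild-type replicate 2, 62 without nht1 replicate 1 and 51 without nht1 replicate 2.

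Of the 25 gene lists fixed before the data were examined, 5 stood apart from the other genes in this comparison (camera, Benjamini-Hochberg adjusted over the lists). Core stress genes were higher (adjusted p = 4.79e-05 with the preset correlation; adjusted p = 0.223 with an estimated correlation): 9 of 35 rose, or 12 when adjusted over the list alone, among them caf5, the quinone reductase gene obr1 (1.55, SE 0.17) and the glutathione transferase gene gst2 (1.42, SE 0.19). Nitrogen starvation genes were higher (adjusted p = 0.000981; adjusted p = 0.223 with an estimated correlation), with 3 of 22 that rose, or 7 adjusted over the list alone. They were urg1 (1.43, SE 0.39), the ammonium transporter gene amt1 (0.94, SE 0.19) and the amino acid permease gene per1 (0.84, SE 0.23). Heat shock genes were higher (adjusted p = 0.021; adjusted p = 0.761 with an estimated correlation), with 1 of 16 past the gene test, or 3 adjusted over the list alone: hsp90 (0.49, SE 0.13). Ribosome biogenesis genes were lower (adjusted p = 1.06e-05; adjusted p = 0.239 with an estimated correlation), with 62 of 71 below 0, and ribosomal protein genes also (adjusted p = 0.0139; adjusted p = 0.761 with an estimated correlation), with 77 of 124 below 0. The median log2 fold changes of these 2 lists were small, at -0.15 and -0.06, and no single member of either passed. The heat shock call ended without wild-type replicate 1 or nht1 replicate 2 (adjusted p = 0.113 and 0.464 as the lowest and highest), and the ribosomal protein call without nht1 replicate 1 (0.200). Calls of hsp90, urg1, amt1 and per1 each ended without either nht1 library and without wild-type replicate 2, and those of hsp90 and urg1 also without wild-type replicate 1 (adjusted p over these fits 0.0504 to 0.401). That of urg1 ended without iec5 replicate 1, with DESeq2 (0.0715) and in the fit of 2 groups only (0.0681) as well, and that of per1 with DESeq2 (0.0506).

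Other lists held few called members in the nht1 comparison. Of 124 subtelomeric genes, defined as within 100 kb of the ends of chromosomes I and II, only 59 had enough counts to be tested. Of these 59, 2 rose and 1 fell, or 7 and 3 adjusted over the list alone. Those that rose were isp3 and gal7 (each 1.43), and SPBPB10D8.02c, for an arylsulfatase, was at -0.78 (SE 0.18). Among iron uptake genes 2 of 17 rose, the ferrichrome synthesis genes sib2 (1.23, SE 0.21) and sib1 (0.63, SE 0.13); adjusted over the list alone, 3 rose and 4 fell. Of glucose repressed and hexose transport genes 3 of 29 rose, or 5 adjusted over the list alone: gal7, the glucose transporter gene ght5 (1.20, SE 0.30) and adh1 (0.57, SE 0.13). Of purine, pyrimidine and dNTP synthesis genes, apt1 (-0.76, SE 0.15) and ade9 (-0.70, SE 0.12) fell among 26, and likewise 2 adjusted over the list alone. Of 18 genes for CENP-A and kinetochore assembly, cnp3 fell and ams2, which encodes a GATA-type factor, rose (0.69, SE 0.18), and the same count of 1 each way held adjusted over the list alone. Of 26 mating genes, mfm1, one of several near-identical M-factor pheromone genes, fell (-2.72, SE 0.73), and adjusted over the list alone 2 rose and 1 fell. One member each rose among 19 meiotic transcripts under Mmi1 control (rec10; 2 adjusted over the list alone), 8 zinc response genes (adh4, 0.66, SE 0.16; 2 adjusted over the list alone), 11 phosphate response genes (tgp1, 0.97), 27 other chromatin remodellers (rsc1, 0.71), 18 wtf genes (wtf5, 0.78) and 10 strain marker genes (arg3, 0.72). The last 4 of these lists also had 1 adjusted over the list alone. In the 10 lists with no called member (flocculation, DNA damage, heterochromatin and RNAi factors, histones, INO80 subunits, MBF targets, respiration, ribosomal proteins, ribosome biogenesis and Tf2 retrotransposons), edgeR called 0 of 358 genes, 39 had an unadjusted p under 0.05 and DESeq2 called 2. Adjusted over the list alone 0 were called. In these lists, calls kept in all 8 fits that left out 1 library each were those of cnp3 and rec10. The others named ended in 1 to 5 of these fits (adjusted p 0.0504 to 0.444), always through libraries of wild type, nht1 or, for isp3, iec5 replicate 1. The call of isp3 also ended with DESeq2 (adjusted p = 0.0777) and in the fit of 2 groups only (0.0534), and that of mfm1 with DESeq2 (0.0882). Reads of gal7, SPBPB10D8.02c, apt1, ade9, rec10, tgp1, wtf5 and arg3 are uncertain as to gene, because each overlaps another.

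In the libraries labelled iec1, 374 coding genes rose and 103 fell against wild type among 4652 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The gene osr1 rose by 3.79 (SE 0.24, adjusted p = 1.46e-08) and SPCC70.08c by 3.38 (SE 0.19), from 72.4 ± 18.3 to 752 ± 72.7 CPM (SD, n = 2 each). The genes SPBC609.01 (3.17, SE 0.18), SPCC663.08c (3.09, SE 0.19), nur1 (2.54, SE 0.31) and ppk31, for a protein kinase (2.49, SE 0.17), also rose. The amidase gene SPAC869.01 rose by 3.21 (SE 0.59) from 1.98 ± 1.95 to 18.7 ± 0.742 CPM (SD, n = 2 each), the alpha-galactosidase (melibiase) gene mel1 by 2.88 (SE 0.49) and urg1 by 2.90 (SE 0.35). SPAC9G1.14 (2.93, SE 0.51) overlaps wis4 and is uncertain. Among genes that fell were dus2 (-1.53, SE 0.17), spp27, for a subunit of the RNA polymerase I upstream activation factor (-1.33, SE 0.15), SPBC530.07c (-1.95, SE 0.33) and the oxoprolinase gene SPAC11D3.15 (-1.31, SE 0.13). SPBC887.17 fell from 686 ± 136 to 138 ± 13.6 CPM (SD, n = 2 each; log2 fold change -2.31, SE 0.16), and his6 (-1.34, SE 0.24) and ste4, for an adaptor of the pheromone MAPK cascade (-1.46, SE 0.28), also fell. Each of these 3 overlaps another gene. The siderophore transporter gene str3 had 2 and 0 counts in these libraries against 24 and 19 in wild type, a ratio of wild type to iec1 of 18.2 (95% exact conditional interval 4.75 to 155, counting error only). Calls ended for str3 without either wild-type library or iec1 replicate 2 (adjusted p = 0.0655 to 0.119), for hpz2 (-1.98, SE 0.54) without any 1 of the wild-type and iec1 libraries (0.0535 to 0.166) and with DESeq2 (0.0643), and for the iron oxidase gene fio1 (-1.81, SE 0.39) without wild-type replicate 1 (0.0847). The count of 477 was 295 without wild-type replicate 1, 234 without wild-type replicate 2 and 290 without iec1 replicate 1, the library with the fewest counts.

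Of the fixed lists, 4 stood apart in the libraries labelled iec1 (camera, Benjamini-Hochberg adjusted over the lists). Nitrogen starvation genes were higher (adjusted p = 7.41e-05; adjusted p = 0.258 with an estimated correlation): 7 of 22 rose, or 10 adjusted over the list alone, among them urg1, urg2 (2.26, SE 0.41), amt1 (1.14, SE 0.19) and the oligopeptide transporter gene isp4 (1.12, SE 0.28). Core stress genes were higher (adjusted p = 0.0158; adjusted p = 0.302 with an estimated correlation), with 12 of 35 that rose, or 15 up and 1 down adjusted over the list alone: caf5 (2.32, SE 0.22), gst2 (1.95, SE 0.19), obr1 (1.94, SE 0.17) and pyp2, for a stress MAPK phosphatase (1.98, SE 0.39), which overlaps emc10. Ribosome biogenesis genes were lower (adjusted p = 9.68e-07; adjusted p = 0.275 with an estimated correlation), with 4 of 71 that fell, likewise 4 adjusted over the list alone: utp15 (-0.55, SE 0.13), nop4 (-0.50, SE 0.13), utp3 (-0.45, SE 0.13) and noc201 (-0.45, SE 0.13). Ribosomal protein genes were lower (adjusted p = 0.0242, and adjusted p = 0.907 with an estimated correlation), though no single one of 124 passed. The median log2 fold changes of the ribosomal protein and ribosome biogenesis genes were small, at -0.07 and -0.22. The core stress call ended without iec1 replicate 2 (adjusted p = 0.107), and the ribosomal protein call without wild-type replicate 2 or iec1 replicate 2 (0.0523 and 0.904). Calls of the 4 ribosome biogenesis genes and of isp4 ended in 2 or 3 fits each that left out a wild-type or iec1 library (adjusted p = 0.0501 to 0.221). Those of utp3 and noc201 also ended in the fit of 2 groups only (adjusted p = 0.0690 and 0.0691). Each of these 4 genes overlaps another.

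Among subtelomeric genes 12 of the 59 tested rose and 3 fell in the libraries labelled iec1, or 17 and 7 adjusted over the list alone. The list did not stand apart by camera (adjusted p = 0.499, and adjusted p = 0.836 with an estimated correlation). SPAC869.01 and mel1, both near the right end of chromosome I, and aes1 (1.74, SE 0.46) rose, and str3 fell. Meiotic transcripts under Mmi1 control included 4 of 19 that rose, likewise 4 adjusted over the list alone: rec10 (1.95, SE 0.23), mug4 (1.87, SE 0.36), spo5 (1.74, SE 0.42), and rec11, for a meiotic cohesin subunit (0.90, SE 0.24). Iron uptake genes went both ways, with 4 of 17 up and 3 down (4 and 4 adjusted over the list alone): sib2 (1.21, SE 0.21) and php4, for a repressor of iron-using genes (1.13, SE 0.21), rose, and str3 and fio1 fell. Of glucose repressed and hexose transport genes, 7 of 29 rose and 2 fell (9 and 2 adjusted over the list alone), among them mel1, gal7 (3.03-fold), ght5 (1.13, SE 0.30) and the pyruvate decarboxylase gene pdc201 (0.94, SE 0.23). Of mating genes 3 of 26 rose and 1 fell (5 and 1 adjusted over the list alone), with sxa2 (1.08), the formin gene fus1 (0.81) and mam1 (0.57) up and ste4 down. Of 38 heterochromatin and RNAi factors, tas3, a subunit of the RITS complex (0.70, SE 0.19), and dsh1 (0.62, SE 0.17) rose, likewise 2 adjusted over the list alone. Kinetochore assembly genes cnp20 (2.83-fold) and ams2 (0.98, SE 0.18) rose and cnp3 (-1.22, SE 0.17) fell among 18, or 2 each way adjusted over the list alone. Among 23 flocculation and cell surface genes 3 rose, likewise 3 adjusted over the list alone, among them pfl9 (1.26) and pfl8 (1.06). Calls of cnp3, ams2, mel1, SPAC869.01, rec10, ste4, sib2 and php4 were kept in all 8 fits that left out 1 library each. The other genes named here lost theirs in 1 to 4 of those fits, each time through a wild-type or iec1 library (adjusted p 0.0507 to 0.282). With DESeq2 the calls of aes1 and cnp20 ended (adjusted p = 0.131 and 0.0614). Of these genes rec10, mug4, spo5, gal7, sxa2, fus1, mam1, ste4 and dsh1 overlap another gene.

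Smaller groups in the libraries labelled iec1 had 1 to 3 called members. Of 26 purine, pyrimidine and dNTP synthesis genes ade7 rose (0.72, SE 0.15) and apt1 (-0.77, SE 0.15) and ade9 (-0.75, SE 0.12) fell, with the same counts of 1 and 2 adjusted over the list alone. Of 29 DNA damage response genes the checkpoint mediator gene crb2 rose (1.15, SE 0.28) and smc6 fell (-0.53, SE 0.14), and 1 each way adjusted over the list alone. One gene rose in each of the lists of MBF targets (cdt1, for a replication licensing factor, 1.30, SE 0.25), other chromatin remodellers (rsc1, for an RSC subunit, 1.16, SE 0.16), wtf genes (wtf5, 1.33, SE 0.20, of a near-identical family), zinc response (adh4, 0.94, SE 0.16), strain markers (arg3, 1.14, SE 0.16) and INO80 subunits (iec1 itself), with 1 adjusted over the list alone in each. Of phosphate response genes tgp1, for a glycerophosphodiester transporter, rose (1.15, SE 0.24), and adjusted over the list alone 1 rose and 1 fell. In the 5 lists with no called member (heat shock proteins, histones, respiration, ribosomal proteins and Tf2 retrotransposons), edgeR called 0 of 179 genes, 12 had an unadjusted p under 0.05 and DESeq2 called 0. Adjusted over the list alone 0 were called. Calls of apt1 and tgp1 ended without wild-type replicate 2 (adjusted p = 0.0535 and 0.0844), that of ade7 without iec1 replicate 1 (0.0523), that of crb2 without wild-type replicate 2 or iec1 replicate 1 (0.116 to 0.181) and that of smc6 without wild-type replicate 1 or iec1 replicate 1 (0.100 to 0.116). The genes apt1, ade9, crb2, smc6, wtf5, arg3 and tgp1 overlap another gene.

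The libraries labelled iec5 had the fewest changed coding genes of the 3 against wild type. Of 4652, 13 rose and 6 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 25 and 12 with a block on the replicate number. The gene osr1 rose by 2.32 (SE 0.23, adjusted p = 5.44e-05), SPCC663.08c 2.64-fold, obr1 by 1.26 (SE 0.17) and SPAC1039.02, for a phosphatase, by 1.23 (SE 0.21). Smaller rises were those of rec10 (1.19, SE 0.24), SPCC70.08c (1.11, SE 0.19) and gst2 (1.997-fold). Among genes that fell were dus2 (-1.66, SE 0.17, adjusted p = 5.44e-05), the flavin oxidoreductase gene SPBC23G7.10c (-2.42, SE 0.42), from 15.8 ± 4.01 to 2.87 ± 1.72 CPM (SD, n = 2 each), and SPBPB10D8.02c (-1.07, SE 0.18). The gene gdt1 (SPAC186.05c, chromosome I, 5540032 to 5541502) had 0 counts in both iec5 libraries and 26 and 20 in the wild-type ones. This is at least 7.50-fold lower than wild type when 3 counts per library are taken as the floor. Both iec5 libraries carry the same strain name, as do those of each other group. An effect of a deletion thus cannot be told apart from another difference of that strain, for gdt1 or any other gene. The count of 19 was 2 without wild-type replicate 1, 9 without wild-type replicate 2 and 9 without iec5 replicate 1. Of 17 named genes called here, osr1 and dus2 kept their calls in all 8 fits that left out 1 library. Those of SPCC663.08c (adjusted p = 0.0615), obr1 (0.0694), SPCC70.08c (0.273) and gdt1 (0.0694) ended without wild-type replicate 1. The call of gst2 ended without wild-type replicate 1 or iec5 replicate 2 (adjusted p = 0.199 to 0.489) and that of SPBC23G7.10c without either wild-type library or iec5 replicate 1 (0.0615 to 0.182). Calls of SPAC1039.02, rec10 and SPBPB10D8.02c ended in 3 to 5 fits that left out libraries of wild type, iec5 or, for rec10, nht1 (adjusted p = 0.0501 to 0.551).

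As lists, ribosomal protein genes (camera adjusted p = 1.35e-05, and adjusted p = 0.693 with an estimated correlation) and ribosome biogenesis genes (adjusted p = 0.00173, and adjusted p = 0.56 with an estimated correlation) were lower in iec5. Of these, 109 of 124 and 59 of 71 were below 0, with small median log2 fold changes of -0.11 and -0.09. No single member passed the test. Core stress genes were higher (adjusted p = 0.00542; adjusted p = 0.56 with an estimated correlation), with obr1 and gst2 that rose among 35, or 6 adjusted over the list alone. The core stress and ribosome biogenesis calls ended without iec5 replicate 2 (adjusted p = 0.0995 and 0.215). Of the 59 subtelomeric genes tested, gdt1 and SPBPB10D8.02c fell, likewise 2 adjusted over the list alone. Of 19 meiotic transcripts under Mmi1 control rec10 rose, and of 16 INO80 subunit genes iec5 itself fell, each also 1 adjusted over the list alone. In the other 21 lists edgeR called 0 of 561 genes, 17 had an unadjusted p under 0.05 and DESeq2 called 0. Adjusted over the list alone 2 were called, 1 heat shock gene and 1 strain marker gene. These 21 were the lists of kinetochore assembly, DNA damage, flocculation, glucose repression, heat shock, heterochromatin and RNAi factors, histones, iron, mating, MBF targets, nitrogen starvation, other remodellers, phosphate, nucleotide synthesis, respiration, ribosomal proteins, ribosome biogenesis, strain markers, Tf2, wtf and zinc. Median, mean and camera direction differed in sign for 9 lists in nht1, 8 in iec1 and 5 in iec5, of which 0 were among the lists called by camera.

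Across the 3 comparisons, 12 coding genes rose and 2 fell in every one. The rises were led by osr1, SPCC663.08c, SPCC70.08c, SPBC609.01 and rec10, and the falls were those of dus2 and SPBPB10D8.02c. With a block on the replicate number, 24 rose and 5 fell in all 3. Of the genes that rose, 140 were shared by nht1 and the libraries labelled iec1, against 11.7 for independent lists, as were 37 of those that fell, against 1.02. The correlation of log2 fold changes across the 4652 genes, which are not independent replicates, was 0.813 between nht1 and iec1, 0.550 between nht1 and iec5 and 0.506 between iec1 and iec5. Because all 3 comparisons use the same wild-type libraries, simulated unchanged groups gave mean correlations of 0.484, 0.492 and 0.488, with highest values of 0.543, 0.542 and 0.554. The correlation of iec1 with iec5 thus lay below its simulated maximum, and that of nht1 with iec5 just above its own. The simulated groups held no change, so their correlations set no limit for groups that do change. The covariances were 0.151, 0.0615 and 0.0701, each above its simulated mean of 0.0306, 0.0305 and 0.0306. For these correlations and counts the controls were not split, since each part would keep 1 library, so some of the excess may come from the shared controls. Genes chosen in 1 library each of wild type, nht1 and iec1 kept a median nht1 and iec1 change of 0.872 to 1.01 in the other libraries. This argues against scatter between the 2 wild-type libraries as the whole source of those rises. A deviation common to both wild-type libraries would remain under this choice, so it is not excluded. Pairs that included iec5 shared 12 rises and 3 falls with nht1 (independent lists 0.408 and 0.0593) and 13 rises and 2 falls with iec1 (1.05 and 0.133). Simulated unchanged groups shared at most 1 call in either direction for each pair, and at most 1 rise and 0 falls across all 3. They had means of only 0.36 to 0.43 calls per comparison, so few shared calls were bound to follow. How scatter of shared controls adds to overlap between groups that do change was not simulated. The iec5 call of SPBC609.01 ended in the fit of 2 groups only (adjusted p = 0.158) and without any 1 of the wild-type, nht1 and iec5 libraries (0.0620 to 0.449). The count of 14 was 2 without wild-type replicate 1, 8 without wild-type replicate 2 and 8 without iec5 replicate 1.

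**Figure D2:**
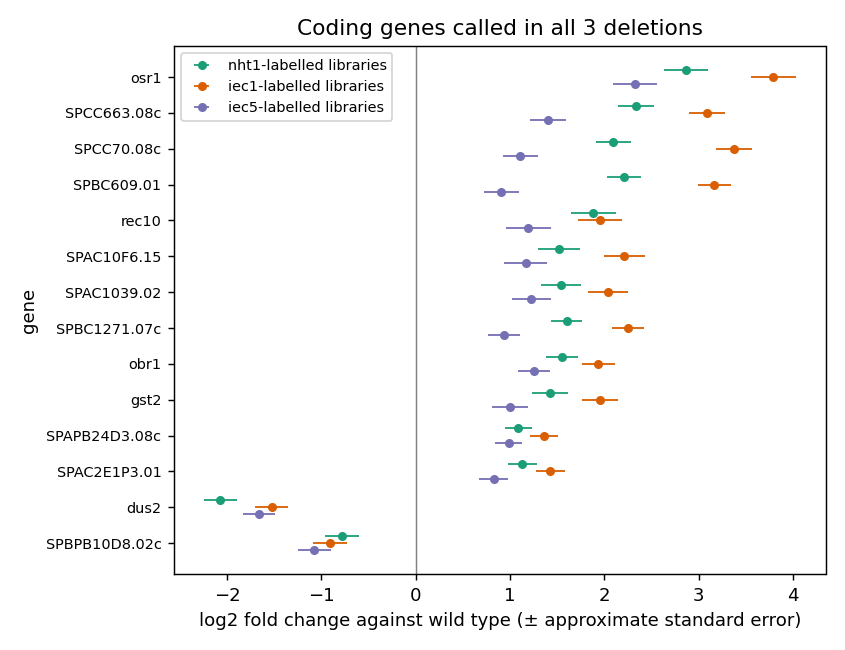
Log2 fold change against wild type (horizontal axis, with its approximate standard error) of the 14 coding genes (vertical axis) called in the same direction in all 3 deletions; each point is the fitted value for 1 deletion from 2 libraries against 2 wild-type libraries. The values of osr1 are 2.87, 3.79 and 2.32 for nht1, iec1 and iec5, and those of dus2 are -2.07, -1.53 and -1.66.

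The deletion groups, as labelled, were also tested directly against each other. Of 4652 genes, edgeR called 7 between the libraries labelled iec1 and nht1, 25 between iec5 and nht1 and 219 between iec1 and iec5. With a block on the replicate number it called 25, 53 and 329 in the same order. The kinase gene ppk31 was higher in iec1 than in nht1 (1.10, SE 0.15, adjusted p = 0.00399) and than in iec5 (2.52, SE 0.17, adjusted p = 1.4e-07). The CENP-C gene cnp3 was higher in iec5 than in nht1 (1.18, SE 0.17) and lower in iec1 than in iec5 (-1.35, SE 0.17). SPBC23G7.10c, at 2118146 to 2119536 on chromosome II, was taken up after its values were seen: it rose in iec1 (2.03, SE 0.29) and fell in iec5 (-2.42, SE 0.42), and the 2 differed (4.44, SE 0.37, adjusted p = 1.47e-06). The call of ppk31 between iec1 and nht1 ended without either nht1 library (adjusted p = 0.0949 to 0.278), that of cnp3 between iec5 and nht1 without nht1 replicate 2 (0.0728), and that of SPBC23G7.10c in iec5 against wild type without either wild-type library or iec5 replicate 1 (0.0615 to 0.182). The count of 7 was 20 with DESeq2 and 32 in the fit of 2 groups only. It was 0 without nht1 replicate 1, 1 without nht1 replicate 2 and 11 without iec5 replicate 2. The count of 25 was 11 without nht1 replicate 1, 4 without nht1 replicate 2 and 15 without either iec5 library. That of 219 was 125 without iec1 replicate 1, 115 without iec5 replicate 1 and 86 without iec5 replicate 2.

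Among 1096 noncoding features tested, 58 rose and 14 fell in nht1, 135 rose and 26 fell in the libraries labelled iec1, and 11 rose and 5 fell in iec5 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). SPNCRNA.1292, which lies opposite SPCC70.08c, rose by 2.06 (SE 0.17) in nht1 and 3.34 (SE 0.18) in iec1. SPNCRNA.560, opposite atg1801, rose by 2.15 (SE 0.27) and 2.34 (SE 0.27) in nht1 and iec1 and 2.63-fold in iec5. SPNCRNA.1585, opposite caf5, rose by 2.15 (SE 0.21) in nht1, SPNCRNA.1421, opposite ppk31, by 2.58 (SE 0.17) in iec1, and SPNCRNA.793, opposite obr1, by 1.26 (SE 0.17) in iec5. SPNCRNA.610, opposite SPAC11D3.15, fell in nht1 (-1.01, SE 0.21) and iec1 (-1.93, SE 0.22), and SPNCRNA.1307, opposite SPBPB10D8.02c, fell in iec5 (-1.12, SE 0.19). Of the 1528 features, 812 overlap a coding gene on the opposite strand alone, 290 overlap one on their own strand and 426 overlap none. Of these 732, 220 and 144 were tested, and the called features numbered 54, 11 and 7 in nht1, 125, 17 and 19 in iec1, and 13, 0 and 3 in iec5. Tested alone, the features that overlap none gave edgeR counts of 0, 6 and 1, with 16, 29 and 10 at unadjusted p under 0.05. DESeq2, run on all features, gave 46, 113 and 15. Over 323 features lying at least 95% inside an opposite-strand gene, the median log2 ratio of their counts to those the gene's read density would give was 0.14 (quartiles -0.06 and 0.41). Reads of such a feature and of the gene opposite it therefore could not be told apart, and values of those features are given as uncertain. The same limit holds for coding genes with a feature opposite them, among them SPCC70.08c, atg1801, caf5, ppk31, obr1, SPAC11D3.15 and SPBPB10D8.02c. Overlaps given for coding genes elsewhere are with other coding genes alone. The count of 72 in nht1 was 37 without wild-type replicate 1, 36 without nht1 replicate 1 and 39 without nht1 replicate 2, and 46 with DESeq2 and 34 in the fit of 2 groups only. That of 161 in iec1 was 107 without iec1 replicate 1, and that of 16 in iec5 was 10 without wild-type replicate 1 and 7 without iec5 replicate 2. The call of SPNCRNA.560 in iec5 ended without wild-type replicate 1 or iec5 replicate 2 (adjusted p = 0.0710 to 0.163).

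**Figure D3:**
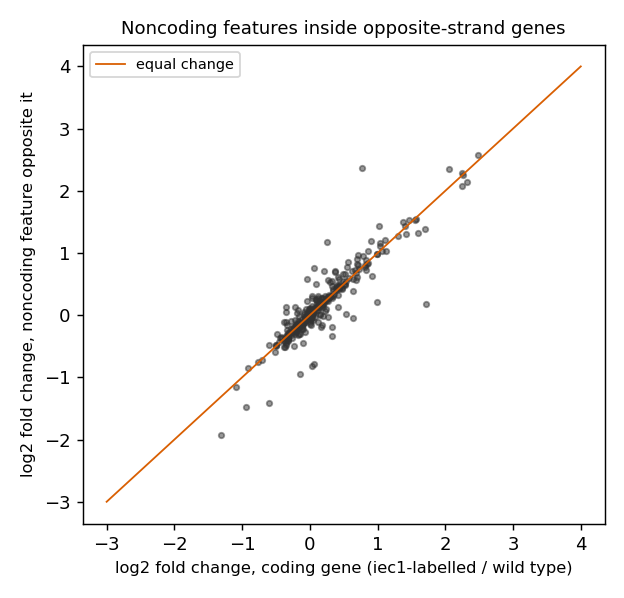
Log2 fold change, libraries labelled iec1 over wild type, of 298 noncoding features (vertical axis) against that of the coding gene on the opposite strand that contains each (horizontal axis); each point is 1 feature and the line marks equal change. The points lie close to the line, with a correlation across features of 0.917.

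Noncoding features within the pericentromeric and mating-type regions were looked at separately, as the series concerns heterochromatin. They were taken by coordinates alone, so some, such as SPNCRNA.1173 (202 CPM in wild type), lie opposite a coding gene and were not silent. Of 42 features in the pericentromeric and mating-type regions, 20 had 0 counts in all libraries and 8 were tested. Of the 8, edgeR called 0 in nht1 (2 at unadjusted p under 0.05, and 0 by DESeq2), 2 in iec1 and 1 in iec5. SPNCRNA.1172 (chromosome III, 1068597 to 1069142), which overlaps no coding gene, had 0 and 7 counts in wild type and 25 and 24 in the libraries labelled iec1 (log2 fold change 3.04, SE 0.78, edgeR adjusted p = 0.00744). The size is uncertain, at 2.06 without wild-type replicate 1 and 7.79 without replicate 2, which leaves wild type at 0 counts. The other 2 tested features that overlap no coding gene had values below 0 in iec1 that did not pass (SPNCRNA.359, -0.63, SE 0.64, adjusted p = 0.588; SPNCRNA.480, -0.91, SE 0.66, adjusted p = 0.411). SPNCRNA.1487 (chromosome II, 2120212 to 2121384) lies opposite mag2, so its counts may include reads of mag2. Its iec1 value was picked after it was seen. By edgeR it was higher in iec1 (0.75, SE 0.21, adjusted p = 0.0149) and lower in iec5 (-1.63, SE 0.23, adjusted p = 0.00012). The call of SPNCRNA.1172 ended without wild-type replicate 1 or iec1 replicate 1 (adjusted p = 0.0597 to 0.0990). That of SPNCRNA.1487 in iec1 ended with DESeq2 (0.0577), without wild-type replicate 2 (0.278) and without iec1 replicate 1 (0.129). The features with 0 counts give no information on silencing, and whether depth or the counting of repeated sequence gave the 0 counts was not tested.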

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

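The tests of thinning and of starvation genes in this part were set before their values were computed, and all other tests of explanations here were chosen after the result was seen. Direct tests between deletions called 7 coding genes for iec1 against nht1, 25 for iec5 against nht1 and 219 for iec1 against iec5 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and the named ones are given here because the difference itself was tested. Directions for iec1 are those of the libraries so labelled.

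In iec1 against nht1, SPBC18H10.05 was higher by 1.78 and bir1, for survivin, by 1.08, and each overlaps another gene (swd2 and tcb1). SPCC70.08c was higher by 1.2801, ppk31 by 1.10 and SPBC609.01 by 0.96, and SPBC887.17, which overlaps hfi1, stood at -0.83. None of these 6 calls was kept in all 8 fits that left out 1 library: they ended without nht1 replicate 1 in every case, without nht1 replicate 2 for all but SPCC70.08c, without iec1 replicate 2 for bir1 and without iec1 replicate 1 for SPBC887.17 (adjusted p = 0.0553 to 0.584).

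In iec5 against nht1, cnp3 was higher by 1.18, SPBC887.17 by 0.98, prf1, for a Paf1 complex protein, by 0.88, SPBC215.11c by 0.78 and spp27 by 0.73. Lower in iec5 were SPBC23G7.10c (-3.48), the iec5 gene (-2.57), uro1 (-1.62) and efm3 (-1.56, overlapping cps3), and gdt1, with 0 counts in iec5, was at least 8.52-fold lower. Calls of gdt1 and SPBC23G7.10c were kept in all 8 fits that left out 1 library. Those of cnp3, SPBC887.17 and efm3 ended without nht1 replicate 2, those of prf1 and iec5 without either nht1 library or iec5 replicate 2, and those of SPBC215.11c, spp27 and uro1 without any 1 of the nht1 and iec5 libraries (adjusted p = 0.0515 to 0.638).

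In iec1 against iec5, SPAC869.01 was higher by 4.52, SPBC23G7.10c by 4.44, urg1 by 2.55 and ppk31 by 2.52, and gdt1 was at least 4.49-fold higher. SPBC887.17 stood at -1.80, fio1 at -1.65, spp27 at -1.38 and cnp3 at -1.35. The fitted value of str3 was -4.04, and its pooled counts gave a ratio of iec5 to iec1 of 18.1 (95% exact conditional interval 4.72 to 155, counting error only, with iec5 counts of 32 and 10). SPBC23G7.10c went in opposite directions against wild type, with 2.03 in iec1 and -2.42 in iec5. The call of fio1 ended without iec5 replicate 1 (-0.53, adjusted p = 0.411), with DESeq2 (0.144) and in the fit of 2 groups only (0.0660). That of gdt1 ended without iec5 replicate 2 (0.0508) and that of str3 without either wild-type library, iec1 replicate 2 or iec5 replicate 1 (0.0565 to 0.302).

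Noncoding features opposite a coding gene changed with that gene. Over 323 such features the median log2 ratio of their counts to those the gene's read density gives was 0.14, and over 298 pairs the fold changes correlated at 0.917, which is what counting without regard to strand would give, so the changes of these features may be those of the genes. Transcripts of their own could still change elsewhere: 13.2% of the 144 tested features that overlap no coding gene passed in iec1, though with those features tested alone 6 passed. Overlap between true antisense transcripts and genes was not separable at the level of counts, so values of the genes may hold antisense reads too.

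Reads of the deleted genes remained in the nht1 and iec1 libraries. For nht1 the ratio to wild type was 0.663 (SD 0.174), against 13.1% of the counted length outside the coding sequence. At even read density, untranslated parts left in place would give fewer reads than that. The limit set for rejecting them as the source was not reached, so the test leaves this open. A deletion of only part of the coding sequence might leave such reads and was not tested. For iec1 the ratio was 2.39 (SD 0.221), which a partly removed gene alone would not give unless the part left in place were expressed more. A swap with libraries of another deletion was tested through the lowest iec1 ratio among the nht1 and iec5 libraries, which was 0.896. No library of another deletion thus had clearly lost iec1 reads. This cannot settle a swap, because the share of reads that the iec1 deletion leaves is unknown, and the nht1 libraries kept 0.663 of theirs. A wrong label for the iec1 libraries could give the value only if the strain used itself had raised iec1 reads. Libraries labelled nht1 and iec5 stood at 1.24 and 1.06 times wild type. A construct that raises reads of the remaining sequence could also give the value, and neither was tested.

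Most genes that rose in nht1 also rose in the libraries labelled iec1. Of the iec1 libraries only replicate 1 was shallow (2208165 counts, against 3403361 in replicate 2). After all libraries were thinned to the smallest, 83.6% of the 140 shared rises (77.1% to 87.1% over 10 draws) stayed called. Most of these rises thus did not need unequal depth. The genes were chosen in the same counts that were thinned, so the test cannot exclude other effects of a shallow library. Cultures nearer starvation stay open. Of genes that starvation induces, ste11 and mei2 had a mean log2 fold change of -0.93 over both comparisons, below the limit set beforehand, though no value passed (adjusted p = 0.101 to 0.499). These 2 genes mark only the mating branch of that response, and nitrogen starvation genes were higher in both (20 and 19 of 22 above 0; camera adjusted p = 0.000981 and 7.41e-05; adjusted p = 0.223 and 0.258 with an estimated correlation), which could come from a difference in nutrients or growth. Core stress genes were also higher and ribosome biogenesis lower, with adjusted p = 0.223 and 0.302 (core stress) and adjusted p = 0.239 and 0.275 (ribosome biogenesis) with an estimated correlation.

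A difference between the wild-type strain and all 3 deletion strains would give rises of like size in iec5. Over the 140 shared rises the median ratio of the iec5 change to the mean of the other deletions was 0.368 (0.337 to 0.421), but these genes were chosen for rising in the same libraries. With 140 genes chosen in 1 library each of wild type, nht1 and iec1 and measured in the others, the ratio was 0.283 (0.260 to 0.321 over 8 choices). This argues against such a difference as the whole cause of the rises. Of these genes 70.7% to 80.7% were above 0 in iec5, against 51.5% to 51.6% of all genes, so a smaller common part could remain. Falls were not tested in this way, and the 2 called in all 3 deletions were of like size in iec5. They were dus2 (-2.07 in nht1, -1.53 in iec1 and -1.66 in iec5) and SPBPB10D8.02c (-0.78, -0.91 and -1.07). For these falls such a difference stays open. Camera also called core stress genes higher, and ribosome biogenesis and ribosomal protein genes lower, in all 3 comparisons. A common difference could give this, as could a shift in the wild-type libraries that all 3 comparisons share. For ribosomal proteins the adjusted p of camera was 0.0139 (nht1), 0.0242 (iec1) and 1.35e-05 (iec5). With an estimated correlation these lists were not called. An effect of losing subunits of 1 complex stays among the open explanations, untested beyond the labels.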

How the results depend on the processing

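Which features to test alone for lack of overlap was chosen after the result was seen, and all other alternatives before. RLE or own normalization and no low-count filter kept every named call and moved no count by over 1.5 times. DESeq2 lost 15 of 181 named calls and fits of 2 groups only 12 of 180. Counts over the 8 fits that left out 1 library ran from 51 to 243 (nht1), 234 to 484 (iec1), 2 to 22 (iec5), 0 to 11 (iec1 against nht1), 4 to 34 (iec5 against nht1) and 86 to 210 (iec1 against iec5). For noncoding features they ran from 36 to 75, 107 to 163 and 7 to 17, for genes shared by all 3 deletions from 2 to 17, and for lists from 4 to 5, 3 to 5 and 1 to 5. In these fits 284 of 1448 named calls were lost, from 101 of 181 pairs of gene and comparison; fewer samples give less power. A log2 fold change of at least 1 left 66, 176 and 12 coding genes against wild type, 4, 11 and 92 between deletions, 28, 74 and 10 noncoding features and 8 shared genes, as this filter must lower them. DESeq2 gave 20 genes for iec1 against nht1 and 46 noncoding features for nht1, and fits of 2 groups only gave 32 and 34; the cause was not tested. Lists called fell to 0, 0 and 0 with an estimated correlation, and fry called 2 for nht1, 0 for iec5 and 4 for iec1, where ribosomal proteins were lost (adjusted p = 0.603) and subtelomeric genes gained (0.0486); fry tests a list against no change and camera against the other genes. Nothing in the labels says that a replicate number marks a shared batch, and samples were not treated as paired. Correlations of same-number residuals were -0.0694 to 0.274, with 3 of 6 above 0.1, while the second principal component (13.8% of variance) was positive for replicate 1 and negative for replicate 2 in all 4 groups, so a shared batch stays open. A block on the numbers gave 356, 695, 37, 25, 53 and 329 coding genes (nht1, iec1, iec5, iec1 against nht1, iec5 against nht1, iec1 against iec5), 115 noncoding features for nht1, 29 shared genes and 5 lists for iec5, and ended no named call. Falls alone went from 103 to 210 in iec1 under the block. Noncoding features that overlap no coding gene, tested alone (144), gave edgeR counts of 0, 6 and 1, with 16, 29 and 10 at unadjusted p under 0.05; DESeq2 on all features gave 46, 113 and 15. Values that changed sign, none of them called, were Tf2-8 in nht1 without wild-type replicate 1 (0.14; lowest -2.27, without nht1 replicate 2) and in iec1 without iec1 replicate 2 (-0.32; highest 2.20, without wild-type replicate 1), and in iec5 pho84 without wild-type replicate 1 (0.13, against -0.71 without replicate 2) and hhf3 without wild-type replicate 2 (0.007173, against -0.46 without replicate 1); the cause was not tested. Recovery of simulated 1.5-fold changes was 32.8% to 43.3%, and whether depth or the scatter between 2 replicates limits it was not tested. A count of 3 is worth up to 1.36 CPM.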

Other observations

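The tests in this part were chosen after the result was seen, as were the genes named in it. A run of 5 neighbouring genes on chromosome III, from amt1 (2068977) to SPCC576.02 (2084027), rose in the libraries labelled iec1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Beside amt1 (1.14, SE 0.19) they were SPCPB1C11.02 (1.96, SE 0.35), SPCPB1C11.03 (1.03, SE 0.19), xan1, for a xanthine dioxygenase (2.04, SE 0.37), and SPCC576.02 (1.84, SE 0.19). In nht1, amt1, SPCPB1C11.02 (1.53, SE 0.36) and SPCC576.02 (1.34, SE 0.19) passed, and xan1 (1.33, adjusted p = 0.0607) and SPCPB1C11.03 (0.58, adjusted p = 0.0992) did not. The uricase gene uro1, on the same pathway of purine breakdown as xan1, rose by 2.47 (SE 0.34) in iec1, and in iec5 its value was 0.09 (adjusted p = 0.993). The neighbours osr2 and gst2 rose by 1.76 (SE 0.16) and 1.95 (SE 0.19) in iec1 and by 1.398 (SE 0.16) and 1.42 (SE 0.19) in nht1. Fits that left out 1 library were not summarised for the genes of this paragraph that the naming rule did not pick.

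Genes that rose lay next to each other more often than random draws of as many tested genes. Non-overlapping neighbours that both rose numbered 12 pairs in nht1 (mean of 10000 random draws 3.13, upper 95% limit 6, permutation p = 3e-04) and 42 in the libraries labelled iec1 (mean 20.5, limit 28, permutation p = 1e-04, the smallest value these draws can give). Pairs include osr1 with SPCC663.08c and sib1 with sib2. Shared local regulation might give such pairs, but reads that run from 1 gene into the next could too, and the draws do not tell these apart.

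Genes that rose in the libraries labelled iec1 had a median of 47.0 CPM in wild type, against 79.0 for the other tested genes, a ratio of 0.595 (0.510 to 0.725). The limit set for weakly expressed genes being the ones that rise was under 0.5, and that for no such tendency at least 0.8. The interval lies between these limits. The same wild-type libraries were used to call the rises, which by itself tends to lower this median, so the test leaves the question open.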
